A study of Homo sapiens with 12 samples.

How the data were processed

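RNA from the human breast cancer cell line MCF7 was measured on 12 Clariom S arrays, a short-oligonucleotide expression array with 1 sample per array. Total RNA was extracted with a phenol reagent and silica columns and labelled with biotin, per the labels. The authors deposited 1 table of log2 values with 27189 rows and 12 columns, ranging from 3.29 to 14.66. The values were made with RMA (background correction, quantile normalization and median polish of the probes of a probe set) in Affymetrix Expression Console, per the submitters' processing notes, which give no version. These notes also name the mouse build mm10, whereas the labels give Homo sapiens and the probe set names of the deposited table end in a human suffix. The probe sets were therefore read as human, and no coordinates are given, because those notes name no human build. Quantile normalization gives the arrays nearly the same distribution, so a change of total RNA per cell cannot be seen in these values.

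The rows were divided by their names into 21448 gene probe sets, 2197 exon controls, 612 intron controls, 2555 features named by a number alone, 63 ERCC spike-in features and 314 other controls. Only the gene probe sets entered the comparisons. The platform annotation gave 17709 of them 1 gene symbol and none several, and 3739 were unnamed here. All 17709 were matched to the RefSeq gene table (assembly GRCh38.p14) through their gene identifier, and 0 symbols changed. That table was used for names and for which genes neighbour each other. In all, 22 probe sets repeated a symbol, and a gene list took the brightest probe set of a gene.

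Arrays were grouped by their labels into wild type, scramble (CRISPR-Cas9 with a control guide) and JMJD6 knockout, with 4 arrays each. The scramble arrays came from lines SCR1 and SCR2 and the knockout arrays from lines KO8 and KO16, with 2 arrays per line. Some second arrays of a line carry the number 1b, and no source used here says whether arrays of a line came from separate cultures. The p-values therefore measure the spread between these samples, which may be technical. The number of arrays and lines limits the precision.

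Groups were compared with limma 3.58.1 in R 4.3.3 on the log2 values as deposited. All 12 arrays entered a single fit with a mean per group, the line as a random block (duplicateCorrelation, estimated correlation 0.106) and eBayes moderation (9 residual and 5.19 prior degrees of freedom). Lines were compared in a second fit with a mean per line (7 residual degrees of freedom). P-values were adjusted by Benjamini-Hochberg over the 21448 probe sets, and a probe set passed at an adjusted p under 0.05. A probe set is called higher (rose) or lower (fell) only where it passed. All tests were two-sided. The array has no detection flags, so the 95th percentile of the intron controls of each array served as its background level. Where every array of a group lay below it, the fold is given as "at least N-fold", from the brighter group's mean against the mean of the higher of the background level and the probe set's own value in the dimmer group. Where 2 or 3 of the 4 arrays lay below it, the same bound is given with the number of arrays above it, a choice made after the values were seen. The folds of IFIT3, IFIH1 and TNFSF10 against scramble, of CPE and KIF14 in knockout and of IFI44 against wild type rest on 3 of 4 arrays above background in the dimmer group. No fold is given where that ratio is under 1 or both groups lay below.

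Gene lists (32, written from general knowledge) were tested with limma's cameraPR on the moderated statistic, with a preset inter-gene correlation of 0.01 and again with a correlation estimated from the residuals. The set test compares a list with all other probe sets, and its p-values were adjusted over the 32 lists. As an alternative, limma's fry tested each list, with the line block, against no change of its members. Named genes were chosen by a rule: JMJD6; the 14 largest rises and 14 largest falls between knockout and scramble, among named probe sets past the threshold whose line means in both knockout lines lay on the same side of both scramble lines and the wild type; the 5 largest in each direction in the other comparisons; and up to 4 members of each list with the smallest adjusted p. The groups, the tests, the lists, this rule and the alternatives were fixed before the data were examined, except where stated. Genes named outside the rule are said to be so.

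The procedures were tested on simulated data with the real means and spreads and 100 changed probe sets at each of 2 sizes. With a simulated line correlation of 0.1, the estimate came out at -0.00609, below the true value. In the knockout versus scramble comparison, 97 of 100 probe sets changed by 1 on the log2 scale and 54 of 100 changed by 0.5 were then recovered over 21448 probe sets, with 23 unchanged ones called (13.2% of the calls). With the simulated correlation supplied, the same comparison recovered 97 and 47, with 8 unchanged ones called (5.26%). The estimate therefore runs low in a layout of 5 lines, and unchanged probe sets reached an unadjusted p under 0.05 in up to 7.51% of cases. Over a range of simulated correlations, an estimate of 0.106 corresponded to a simulated 0.232. The comparisons keep the estimate, as fixed beforehand, so that their adjusted p-values are somewhat too small, and each count is also given with the correlation of 0.232. For KO16 versus KO8, 80 of 100 probe sets changed by 1 and 12 of 100 changed by 0.5 were recovered. The set test called the raised list of 30 probe sets and 0 of 20 unchanged lists. The simulated probe sets were independent of each other, whereas the estimated correlation of the real lists reached 0.441. This check therefore does not give the rate of false list calls in the real data.

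Alternatives covered the treatment of lines (no block, line means, fixed line means), the arrays in the fit, quantile normalization, median centring, a filter on the dimmest 30% of probe sets, the eBayes prior, array weights, stricter thresholds, a block on the replicate number, and leaving out each array and each line. Wild type and knockout share the replicate numbers 1 and 2, but nothing in the labels says that a number marks a shared culture or day. Scramble and knockout share the numbers 1 and 1b, but the block was run for knockout versus wild type only. A background covariate, the removal of a pair of scramble arrays and the corrected line correlation were added after the data were seen. No scan date was given in the sources used here, so array batches were not tested.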

Results

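Gene expression was measured in MCF7, an estrogen receptor-positive human breast cancer cell line grown in culture, in lines described by the submitters as JMJD6 knockouts made with CRISPR-Cas9 and in control cells. JMJD6 encodes a Jumonji-domain oxygenase of the nucleus that hydroxylates lysines of splicing proteins. The 12 arrays formed 3 groups of 4: untreated wild-type cells, scramble control lines (SCR1 and SCR2, 2 arrays each) and JMJD6 knockout lines (KO8 and KO16, 2 arrays each). The median RMA value of the gene probe sets lay between 8.28 and 8.35 (log2) on every array, and the background level, the 95th percentile of the intron controls, between 6.93 and 7.19. All levels below are RMA values on the log2 scale, as mean ± SD of 4 arrays, and all adjusted p-values are from limma.

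The targeted gene was examined first. JMJD6 (probe set TC1700011818.hg.1) read 10.57 ± 0.05 in wild type, 10.54 ± 0.12 in scramble and 9.89 ± 0.08 in knockout arrays (n = 4 each). The knockout level was 1.57-fold lower than in scramble (log2 fold change -0.65, SE 0.083, adjusted p = 8.2e-05), and each of the 4 knockout arrays (9.8 to 9.97) lay below each of the 8 control arrays (10.44 to 10.71). KO8 and KO16 had the same mean to within 0.01, at 9.89 and 9.9. Scramble and wild type differed by -0.03, with an adjusted p that rounds to 1. The knockout level stayed well above background. The labels do not say which part of the gene was edited, and a transcript with a small deletion can still be read by the array, so this level checks the labels only within that limit and says nothing of the protein.

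The main comparison asked which transcripts differ between JMJD6 knockout lines and the lines that went through CRISPR with a control guide. The leading difference was a rise of interferon-stimulated genes, the antiviral genes switched on by interferon signalling. Of 44 measured members of that list, 43 rose and none fell (44 rose when adjusted over the list alone), with a median log2 fold change of 2.99, or 2.43 with members below background at their bound. EPSTI1, named after its value was seen, was the member that did not pass (adjusted p = 0.086), and it lay below background on every scramble and knockout array. The set test gave an adjusted p of 4.09e-32 with an estimated correlation. IFIT1, which binds viral RNA, and its partner IFIT3 went from 6.92 ± 0.5 and 7.47 ± 0.48 in scramble to 12 ± 0.05 and 12.54 ± 0.1 in knockout arrays (at least 27.3-fold, with 2 of 4 scramble arrays above background, adjusted p = 2.8e-10, and 33.6-fold, SE 0.18 log2 units, adjusted p = 1.2e-10). OAS1, a sensor of double-stranded RNA, was 26.7-fold higher and IFIT2 19.4-fold higher. IFI44, OAS2, CMPK2, HERC5, IFI44L and GBP1 lay below background on every scramble array and were at least 29-fold, 28.7-fold, 14.8-fold, 9.14-fold, 8.23-fold and 7.24-fold higher in the knockout lines. SAMD9, an antiviral restriction factor, was at least 21.1-fold higher (above background on 2 of 4 scramble arrays), and UBE2L6, the conjugating enzyme for ISG15, 13.6-fold higher.

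An interferon gene itself stood among the 14 largest rises. IFNL1, a type III interferon, rose from 8.81 ± 0.23 to 13.16 ± 0.08 (20.5-fold, adjusted p = 2.6e-12). IFIH1, which encodes the RNA sensor MDA5, rose from 7.57 ± 0.63 to 11.54 ± 0.06 (15.7-fold, adjusted p = 2.2e-08). The remaining interferon genes were looked up after these values were seen. IFNB1, the type I interferon of non-immune cells, rose from 7.14 ± 0.22, above background on 1 of 4 scramble arrays, to 10.42 ± 0.14 (at least 9.27-fold, adjusted p = 2.6e-10). IFNL2 and IFNL3 rose by 2.86 and 1.96, but their sequences are nearly identical, so that their probes cannot be told apart with certainty. Of 13 IFNA genes on the array, 1 passed (IFNA17, adjusted p = 0.025), but it lay below background on every scramble and knockout array, so no fold is given. IFNA genes also resemble each other. RIGI, the RNA sensor RIG-I, rose by 3.68 (adjusted p = 2e-09), whereas CGAS, a sensor of DNA in the cytosol, read 8.79 in scramble and 8.93 in knockout arrays (log2 fold change 0.14, adjusted p = 0.53).

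**Figure D1:**
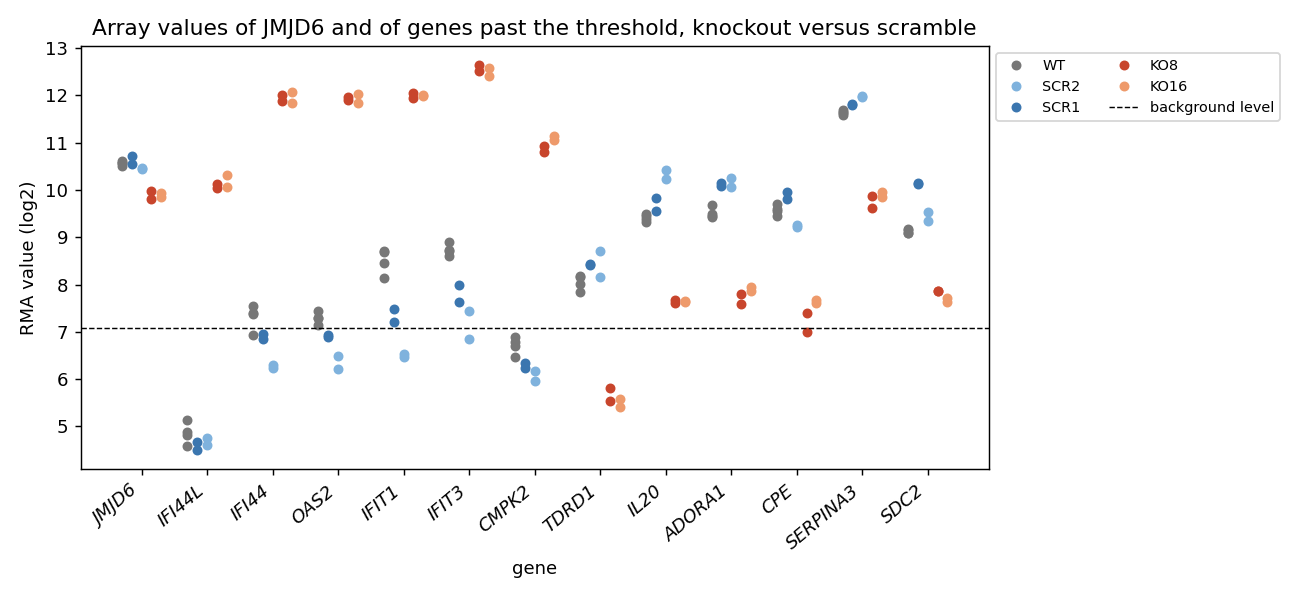
Each point is the RMA value (log2, vertical axis) of 1 array for JMJD6, the 6 largest rises and the 6 largest falls between knockout and scramble chosen by rule; colours mark the lines, WT with 4 arrays and the others with 2, and the dashed line the mean background level of 7.09. The knockout arrays have a mean of 12 for IFIT1 against 6.92 in scramble, and of 9.89 for JMJD6 against 10.54.

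Genes that prepare and present peptides on MHC class I rose as a group. Of 17 measured members, 14 rose and 1 fell (15 and 2 adjusted over the list alone), with a median log2 fold change of 1.37 (adjusted p = 1.79e-48 with an estimated correlation). The immunoproteasome subunits PSMB9 and PSMB8 were 26.8-fold and 12.8-fold higher, the peptide transporter subunit TAP1 7.39-fold higher and the heavy chain HLA-C 5.29-fold higher. Class I heavy chains resemble each other, so single HLA values are uncertain. The member that fell, by 0.39, was PDIA3, a chaperone of the endoplasmic reticulum named after its value was seen. In the NF-kB and inflammatory list 6 of 26 members rose and 1 fell (7 and 1 adjusted over the list alone), with a median of 0.03 and a mean of 0.36 (adjusted p = 0.00547 with an estimated correlation). TNFAIP3 and NFKBIA, feedback inhibitors of NF-kB, were 8-fold and 2.11-fold higher, and the growth factor gene CSF1, above background on 1 of 4 scramble arrays, was at least 5.98-fold higher. IL6 passed the test but lay below background on every scramble array and on 3 of 4 knockout arrays. Its bound came out under 1, so no fold is given. Among apoptosis regulators 6 of 31 rose and 1 fell (the same adjusted over the list alone; median 0.03, adjusted p = 0.0268, and 0.117 with an estimated correlation), led by TNFSF10, the death ligand TRAIL, at 5.09-fold.

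Cell cycle genes were lower. Of 45 measured genes of G2 phase and mitosis, 33 fell and none rose (37 and 1 adjusted over the list alone), with a median log2 fold change of -0.55 (adjusted p = 0.0475 with an estimated correlation). The kinesin KIF14 was 2.28-fold lower, the kinesin KIF4A, above background on 2 of 4 knockout arrays, at least 2.14-fold, the spindle checkpoint gene MAD2L1 1.72-fold and the mitotic kinase AURKA 1.59-fold. Of 43 genes of the G1/S transition, 21 fell and none rose (27 and 0 adjusted over the list alone), with a median of -0.37 (adjusted p = 6.14e-10, and 0.0905 with an estimated correlation). Among them GINS2, of the replicative helicase, was 1.76-fold lower, and RRM2 and TYMS, which make nucleotides for DNA synthesis, were 1.69-fold and 1.6-fold lower. Replication histone genes went both ways, with 4 rises and 4 falls among 39 (6 and 6 adjusted over the list alone; adjusted p = 0.938). Of 27 p53 targets 1 rose and 3 fell (1 and 7 adjusted over the list alone; adjusted p = 0.325, and 0.0417 without SCR1 replicate 1).

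Estrogen-induced genes, a hallmark of MCF7 cells, were lower on balance. Of 29 measured, 15 fell and 4 rose (the same adjusted over the list alone), with a median of -0.31 (adjusted p = 0.000519, and 0.0905 with an estimated correlation). The transcription factor MYB was 2.23-fold lower and the GTPase RAB31 2.15-fold lower. The progesterone receptor gene PGR dropped below background on every knockout array and was at least 2.51-fold lower, whereas the potassium channel gene KCNK5 was 2.03-fold higher. Luminal epithelial markers included 7 falls and 2 rises among 28 (10 and 3 adjusted over the list alone; adjusted p = 0.0867), with SPDEF 2.61-fold lower and the keratin KRT7 1.67-fold higher. In the basal epithelial list 6 of 20 rose and none fell (7 and 0 adjusted over the list alone), while the median was -0.02 and the mean 0.26 (adjusted p = 0.0117, and 0.237 with an estimated correlation). The caveolins CAV2 and CAV1 led it, at 3.11-fold and 3.05-fold. Mesenchymal genes had 5 rises and 2 falls among 33 (8 and 4 adjusted over the list alone; adjusted p = 0.117), and epithelial junction genes 2 and 2 among 22 (3 and 2 adjusted over the list alone; adjusted p = 0.611), with the tight junction gene CLDN1 4.33-fold higher. Without SCR2 replicate 1 the call of the basal list was lost (adjusted p = 0.0802), and without SCR2 replicate 1b the luminal list gained one (0.0473).

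The largest falls outside these lists were in genes of varied function. TDRD1, a Tudor-domain gene of germ cells, dropped below background on every knockout array and was at least 2.54-fold lower. The cytokine gene IL20 fell from 10.02 ± 0.39 to 7.64 ± 0.03 (5.19-fold, adjusted p = 3.6e-08), and the adenosine receptor ADORA1 from 10.14 ± 0.09 to 7.8 ± 0.16 (5.06-fold, adjusted p = 5.3e-10). CPE, a carboxypeptidase of hormone granules, was 4.43-fold lower, the protease inhibitor SERPINA3 4.19-fold and the syndecan SDC2 4.06-fold. The non-coding RNA LINC01588, the calcification inhibitor MGP, ELAPOR1, the kinase DCLK1, and TMT1A were 3.37-fold, 3.08-fold, 3.06-fold, 2.8-fold and 2.74-fold lower, and the glucuronosyltransferase UGT2B15 at least 2.59-fold (above background on 2 of 4 knockout arrays). MAT1A, a methionine adenosyltransferase, lay below background in the knockout lines and was at least 1.25-fold lower.

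Immediate early genes, the first responders to growth factors and stress, included 12 rises and 3 falls among 28 (14 and 4 adjusted over the list alone; median 0.19, adjusted p = 0.0111 with an estimated correlation), with ATF3 2.83-fold and DUSP1 1.8-fold higher. TGF-beta and BMP genes included 11 rises and 1 fall among 26 (the same adjusted over the list alone; median 0.17, adjusted p = 0.00821, and 0.118 with an estimated correlation). The fall was LTBP1, which stores latent TGF-beta, at 2.55-fold, and BMPR1B, a BMP receptor, rose at least 1.89-fold. Of 18 glycolysis genes 7 fell and 1 rose (9 and 1 adjusted over the list alone; median -0.27, adjusted p = 0.00547 with an estimated correlation), with PGK1 1.98-fold and PKM 1.75-fold lower. Genes that neighbour JMJD6 had 4 falls among 19 (5 adjusted over the list alone; median -0.19, adjusted p = 0.0022, and 0.153 with an estimated correlation), led by SEPTIN9 at 1.98-fold and MXRA7 at 1.49-fold.

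JMJD6 has been tied to splicing, and the set test gave no call for the list of splicing factors and JMJD6 partners. Of 34 measured, 2 rose (CLK1 and CDK9, by 0.57 and 0.29) and 1 fell (HNRNPA2B1, by 0.26), with 1 and 0 adjusted over the list alone (adjusted p = 0.892). CDK9 and HNRNPA2B1 did not pass with the line correlation of 0.232 (adjusted p = 0.0728 and 0.0781), nor without KO8 replicate 2 (0.123 and 0.112), KO16 replicate 1b (0.0584 and 0.137), SCR1 replicate 1b (0.109 and 0.147) or SCR2 replicate 1b (0.172 and 0.156), CDK9 also not without KO16 replicate 1 (0.0991), and HNRNPA2B1 not without KO8 replicate 1 (0.0517) or wild-type replicates 1 and 4 (0.0509 and 0.0521). The array sums over exons and does not measure splicing. Among the other Jumonji and related oxygenases 3 rose and 3 fell of 39 (3 and 5 adjusted over the list alone; adjusted p = 0.893), with RIOX1 1.34-fold lower. Endoplasmic reticulum stress genes had 3 rises and 11 falls among 24 (3 and 13 adjusted over the list alone; adjusted p = 0.102, and 0.0417 without SCR1 replicate 1), with XBP1 1.48-fold lower and PPP1R15A 2.05-fold higher. Receptor tyrosine kinases had 4 rises and 3 falls among 27 (4 and 4 adjusted over the list alone; adjusted p = 0.892), with FGFR2 2.88-fold higher. The set test also gave no call for hypoxia genes (3 rises and 3 falls of 28, adjusted p = 0.727), amino acid metabolism (1 and 5 of 23, 0.264), cholesterol synthesis (0 and 4 of 20, 0.892), fatty acid metabolism (3 and 1 of 21, 0.893), ribosomal proteins (0 and 2 of 33, 0.13, and 0.0255 without SCR1 replicate 1), MYC and ribosome biogenesis (0 and 1 of 26, 0.892), oxidative phosphorylation (1 and 3 of 41, 0.408) and genes of the regions amplified in MCF7 (2 and 6 of 28, 0.642). It gave none for markers of other cell types, with 1 rise and 1 fall of 16 for fibroblasts (0.642), 0 and 1 of 17 for immune cells (0.775) and 0 and 0 of 14 for endothelium (0.884). Over the 11 lists of these last 2 sentences, the counts adjusted over each list alone were 3 and 4, 2 and 6, 4 and 4, 3 and 3, 0 and 2, 0 and 0, 1 and 3, 2 and 7, 1 and 2, 0 and 0, and 0 and 0, in the same order. Median and set test differed in sign for basal epithelial genes (median -0.02, direction up), junction genes (median -0.02, direction up), splicing (-0.01, up), cholesterol synthesis (0.06, down), MYC targets (0.01, down) and Jumonji genes (0.02, down).

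**Figure D2:**
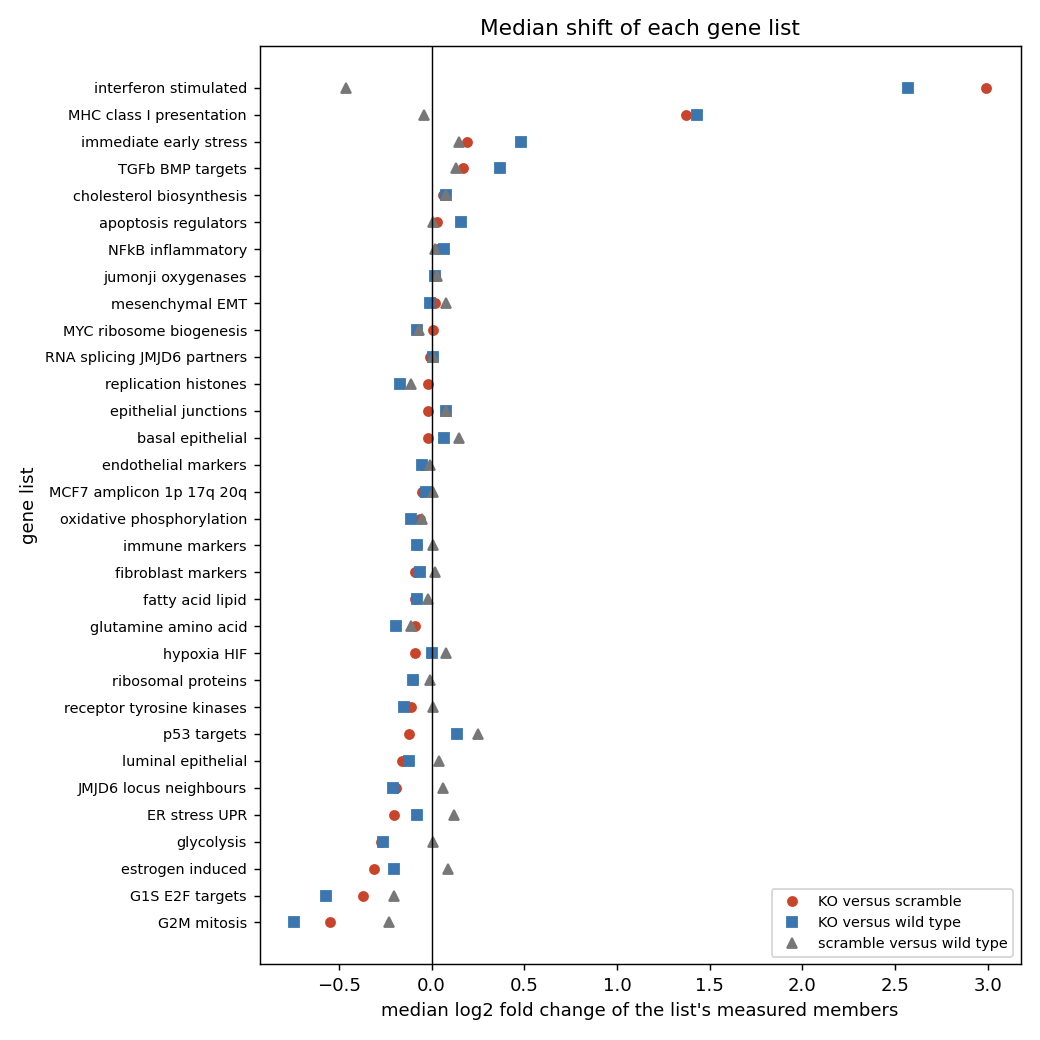
Median log2 fold change (horizontal axis) of the measured members of each of 32 gene lists (vertical axis) in knockout versus scramble (circles), knockout versus wild type (squares) and scramble versus wild type (triangles). The interferon list lies at 2.99 and 2.57 in the knockout comparisons and at -0.46 in scramble versus wild type, and the G2 and mitosis list at -0.55, -0.74 and -0.23.

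In all, 2950 of 21448 probe sets differed between knockout and scramble, of which 1462 were higher and 1488 lower in the knockout lines. This balance depended on the scaling. The counts were 1632 higher and 1584 lower with quantile normalization, 1616 and 1192 with median centring, and 1881 and 2694 with the background covariate. The larger changes were mostly rises: 298 probe sets rose and 64 fell by 1 or more on the log2 scale, and 39 rose and 0 fell by 3 or more. All 2950 moved the same way in KO8 minus SCR1 and in KO16 minus SCR2, 2 differences with no array in common, and across all probe sets these differences correlated at r = 0.79 (Spearman 0.56), or 0.64 (0.3) with the scramble lines exchanged. Probe sets are not independent replicates, and the calls were made on the same arrays. With the line correlation set to 0.232 in place of the low-running estimate, 2326 probe sets passed (1179 higher and 1147 lower). Averaging each line to 1 value gave 1397, and the count became 1859 without SCR2 replicate 1b, 1941 without SCR1 replicate 1b and 5213 without SCR2 replicate 1.

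The knockout lines were also set against wild-type cells, the second control of the design. The 4 wild-type arrays count as 1 line in the fit, so a spread between wild-type lines was not measured. The interferon list again led, with 43 of 44 members higher and none lower and a median of 2.57 (2.15 with bounds; adjusted p = 2.65e-19 with an estimated correlation; 43 adjusted over the list alone). MHC class I genes rose in 14 of 17 cases (15 and 1 fall adjusted over the list alone; median 1.43, adjusted p = 1.05e-38 with an estimated correlation). Mitotic genes fell in 41 of 45 cases (43 and 1 rise adjusted over the list alone; median -0.74, adjusted p = 0.003 with an estimated correlation) and G1/S genes in 35 of 43 (38 adjusted over the list alone; median -0.57, 0.00476). Immediate early genes rose in 15 of 28 cases and fell in 1 (15 and 2 adjusted over the list alone; adjusted p = 7.85e-05 with an estimated correlation), and TGF-beta and BMP genes in 12 of 26 and 1 (15 and 1; 0.00175). The mesenchymal list had 9 rises and 1 fall (the same adjusted over the list alone), with a median of -0.01, a mean of 0.22 and a direction up (0.0288 with an estimated correlation). Calls that held with an estimated correlation were also those of basal genes (7 rises and 1 fall, the same adjusted over the list alone, 0.0132), junction genes (6 and 1, or 7 and 1, 0.0101), NF-kB genes (7 and 0, or 9 and 0, 0.00312) and glycolysis genes (0 and 7, or 1 and 10, 0.0132). The estrogen-induced list, with 4 rises and 13 falls (8 and 14 adjusted over the list alone), had an adjusted p of 0.0184, and 0.258 with an estimated correlation. The same held for histones (adjusted p = 0.0437, and 0.665 with an estimated correlation), oxidative phosphorylation (0.0333 and 0.665), apoptosis regulators (0.0147 and 0.0536) and neighbours of JMJD6 (0.0153 and 0.258), with 4 rises and 11 falls, 0 and 9, 7 and 1, and 0 and 4 (5 and 13, 0 and 9, 8 and 2, and 0 and 4 adjusted over each list alone). The largest rises were OAS2 and IFI44, each 25-fold, PSMB9 at 19-fold, and CMPK2 and IFI44L, below background in wild type, at least 14.9-fold and at least 8.31-fold. LINC01588 was 6-fold lower, CPE 4.46-fold, the actin-binding gene SYNPO2 at least 5.11-fold, the glutamate transporter SLC1A2 at least 3.52-fold (above background on 2 and 1 of 4 knockout arrays) and TDRD1 at least 1.96-fold. In all 3517 probe sets passed, 1803 higher and 1714 lower (2560 with the line correlation of 0.232). Averaging each line to 1 value gave 1097, and the count became 2252 without SCR2 replicate 1b, 6095 without SCR2 replicate 1 and 6318 without SCR1 replicate 1, arrays that enter this comparison only through the shared estimate of spread.

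Calls of these comparisons overlapped. Against both controls 1226 probe sets were higher and 1030 lower in the knockout lines, where independent lists would share 123 and 119, and 4 (CAPN2, NECAB1, TMPRSS4 and GPC6, named after their values were seen) moved in opposite directions. The comparisons share the knockout arrays, which can raise the overlap above that of independent lists. In 5 simulated sets of unchanged groups, with a line correlation of 0.106, at most 0 probe sets were called in both. With nothing changed few calls are made at all, so this count does not measure how far sharing raises the overlap. The fold changes correlated at r = 0.91, with 0.48 in the simulation, and the covariance was 0.118 against 0.00732. With no array in common (KO8 minus scramble against KO16 minus wild type, and the exchange of the knockout lines) the correlation was 0.81 and 0.85.

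Scramble and wild-type cells were compared to show what accompanies the control procedure. The wild type again stood as 1 line. Interferon-stimulated genes were lower in scramble lines, opposite to the knockout lines. Of 44 members 10 fell and none rose (27 and 0 adjusted over the list alone), with a median of -0.46 (adjusted p = 0.000384 with an estimated correlation). IFIT1 was at least 2.4-fold lower (8.49 ± 0.26 in wild type, 6.92 ± 0.5 in scramble, adjusted p = 0.0021), OAS1 2.71-fold and IFIT3 2.41-fold. NECAB1, a calcium-binding protein, and SYNPO2 were 3.15-fold and 2.97-fold lower. The calpain CAPN8, the matrix protease ADAMTS9, the collagen COL5A1 and the endothelin EDN1 were 2.79-fold, 2.39-fold, 2.34-fold and 2.15-fold higher, and AHNAK2, above background on 2 of 4 wild-type arrays, at least 2.25-fold. ADAMTS9 did not pass with the line correlation of 0.232 (adjusted p = 0.128), nor without KO8 replicates 1 and 2 (0.0525 and 0.12), KO16 replicate 1b (0.104), SCR1 replicate 1b (0.262), SCR2 replicate 1b (0.236) or wild-type replicates 1 to 4 (0.0756, 0.0588, 0.104 and 0.121) in turn. Without SCR2 replicate 1b, OAS1 (0.0689) and COL5A1 (0.062) did not pass either. Epithelial junction genes had 3 rises among 22 (4 adjusted over the list alone; adjusted p = 1.9e-05 with an estimated correlation), and TGF-beta and BMP genes 3 among 26 (6, and 1 fall; 0.000474). Mitotic and G1/S genes had no probe set past the threshold (8 and 2 falls adjusted over each list alone) and medians of -0.23 and -0.2 (adjusted p = 0.0495 and 0.0277 with an estimated correlation). The set test was up for basal genes (3 rises among 20, and 5 adjusted over the list alone; adjusted p = 0.00958 with an estimated correlation), immediate early genes (0 among 28, and 4 with 1 fall; 0.00243), mesenchymal genes (2 among 33, and 2; 0.0144) and hypoxia genes (2 among 28, and 3; 0.0247). The basal, junction, mesenchymal, TGF-beta, immediate early, mitotic and G1/S lists moved in the same direction here as in knockout versus wild type. Those comparisons share the wild-type arrays, which can give such agreement without any change. No comparison free of shared arrays was made for these lists. Estrogen-induced, histone, MHC class I, cholesterol, endoplasmic reticulum stress, MYC and oxidative phosphorylation lists had adjusted p-values of 0.0364, 6.95e-07, 0.0292, 0.0152, 0.000177, 0.035 and 0.00463, and 0.369, 0.107, 0.231, 0.45, 0.231, 0.567 and 0.45 with an estimated correlation. Of 27 p53 targets 1 rose (8 adjusted over the list alone), with a list median of 0.25 (adjusted p = 0.00845 with an estimated correlation). In all 136 probe sets passed, 86 higher and 50 lower, and 64 with the line correlation of 0.232. With each line averaged to 1 value 2 passed (CAPN8 and SYNPO2). The count became 82 and 78 without wild-type replicates 1 and 3, 323 and 46 without SCR2 replicates 1 and 1b, 392 and 49 without SCR1 replicates 1 and 1b, 65 without KO8 replicate 2 and 73 without KO16 replicate 1b.

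Lines of the same kind were compared last. No probe set separated KO16 from KO8 in limma (0 of 21448, with 703 at an unadjusted p under 0.05, where 1072 are expected by chance), and array weights gave 1 (CABCOCO1, 0.7 higher in KO16, adjusted p = 0.029, named after its value was seen). The root mean square difference between a KO8 and a KO16 array averaged 0.199, close to that within KO8 (0.196) and within KO16 (0.195). On simulated data this comparison recovered 80 of 100 probe sets changed by 1 and 12 of 100 changed by 0.5, so many differences of that smaller size would go undetected. The same fit found 309 probe sets between SCR2 and SCR1, 225 higher and 84 lower in SCR2. Arrays within SCR1 and within SCR2 differed more (0.263 and 0.277) than within the knockout lines, yet the fit shares a single spread over all lines. On average this overstates the spread of the knockout arrays and understates that of the scramble arrays, so the counts of 0 and 309 are not on an equal footing. The interferon list averaged 8.3 in SCR1, 7.87 in SCR2, 8.6 in wild type, 11 in KO8 and 11.03 in KO16. The count depended on single arrays, with 78 without SCR2 replicate 1, 62 without SCR1 replicate 1, 766 without SCR2 replicate 1b and 916 without SCR1 replicate 1b.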

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

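The tests of the chromosomes of the interferon genes, of the distances between lines, of neighbouring genes and of the MCF7 amplified regions were chosen after the results were seen, as were the background covariate, the corrected line correlation and the look at MTAP, CDKN2B and DMRTA1.

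Interferon-stimulated genes were higher in both knockout lines, with a median log2 fold change of 2.99. The lowest list median over quantile normalization, median centring and a background covariate was 2.99. These settings could not have lowered it much. The deposited values were already quantile normalized, with array medians from 8.28 to 8.35, and the covariate ran only from 6.04 to 6.36. They therefore do not decide whether a shift of array signal or background before normalization had a part. The control procedure of the scramble lines is argued against as a source, since the list had a median of -0.46 in scramble versus wild type. This covers only steps that the scramble lines shared with the knockout lines, and whether cloning was among them was not established. Immune cells in the cultures are also argued against, since their markers had a median of -0.08. A copy-number change of a single chromosome region does not account for the members directly, because the 43 that rose lay on 16 chromosomes with at most 6 on any of them. It also stays open whether loss of JMJD6, another property shared by both knockout lines or a stimulus in those cultures set off the rise. Each of these follows the groups.

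KO8 and KO16 were not told apart, whereas SCR1 and SCR2 were, in a fit with a single spread shared by all lines. Arrays within SCR1 and SCR2 differed more (0.263 and 0.277) than within KO8 and KO16 (0.196 and 0.195), so these line comparisons are not on an equal footing. Arrays of KO8 and KO16 differed by 1.02 times the difference within these lines, against 1.13 for the scramble lines. Single pairs overlapped, at 0.156 to 0.25 between KO8 and KO16 and 0.205 to 0.436 between SCR1 and SCR2, and the scramble pairs include arrays that stand apart in signal, so whether the knockout lines share an origin, such as 1 founder cell or pool, stays open. In 6 of 472 windows of 25 neighbouring genes the median shifted by over 0.25 the same way in KO8 minus SCR1 and KO16 minus SCR2, in 4 with the scramble lines exchanged (r = 0.23 over windows, against 0.61) and in 5 against wild type, where 1000 reorderings of the genes gave at most 1, 0 and 1. This is consistent with a copy-number difference common to both knockout lines but does not establish it. The scramble lines shared 0 such windows against wild type. SCR1 minus wild-type replicates 1 and 2 had 10, and SCR2 minus wild-type replicates 3 and 4 had 7. Neighbour-wide shifts of a single line are therefore not particular to the knockout lines. In that difference of SCR1 they included 4 windows on chromosome X and 5 on chromosome 10, at -0.39 to -0.28 and -0.33 to -0.3. Window medians may also follow array-wide signal, a trend that reordering genes does not imitate. They ran opposite ways in the scramble lines against wild type (r = -0.6), but the cause of this was not settled. The wild-type replicates were not exchanged between the lines, as the scramble lines were above. The 0 shared windows and this opposition may therefore depend on which replicates were set against which line. The same holds for the 5 windows of the knockout lines against wild type. The shift of the clearest window, SCFD1 to GEMIN2 on chromosome 14, remained at 0.44 (0.54 before) with the background covariate. Over all windows of knockout versus scramble those past 0.25 went from 9 to 7, and DRAM2 to SYT6 on chromosome 1 went from 0.27 to 0.24. In scramble versus wild type, with group means compared, 0 of 472 windows passed 0.25, both without and with the covariate. Whether the knockout cultures hold another cell line in place of MCF7 was not decided either. The mean root mean square difference was 0.408 between knockout and wild-type arrays and 0.268 between scramble and wild-type arrays. Against scramble 64 of 21448 probe sets fell by 1 or more on the log2 scale and 0 by 3 or more, while 298 and 39 rose. No array of another cell line was there to set a scale for these sizes. Genes amplified in MCF7 had a median of -0.05, but over members that went both ways (2 rose and 6 fell), and MTAP, beside the CDKN2A region that MCF7 is known to have lost, rose by 1.87, with CDKN2B at 0.9 and DMRTA1 at 0.86. JMJD6 loss and other traits common to both knockout lines therefore stay open for every gene.

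SCR2 and SCR1 differed in their shift from wild type, with 309 probe sets past the threshold against 0 between the knockout lines. Both counts rest on a spread shared by all lines, although arrays within the scramble lines differed more, so they are not on an equal footing. With a background covariate 52 passed, 48 of them among the 309. The covariate read 6.36 and 6.19 on the SCR1 arrays and 6.12 and 6.15 on the SCR2 arrays, so it overlaps with the difference between these lines. Fitting it can remove calls whatever their cause, and the drop does not show whether the signal of single arrays accounts for the count. The origin of this difference in background was not tested.

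Of the 35 splits of the 8 arrays, only the real one gave as many probe sets in each of the 3 group comparisons (1 of 35). Most splits divide the arrays of a line between the groups, so they cannot exclude a chance difference between lines. A split that mixes the groups also adds their difference to the spread, which lowers its count. The real counts and the highest of the other splits were 2950 and 6 for knockout versus scramble, 3517 and 0 for knockout versus wild type, and 136 and 2 for scramble versus wild type. The splits treat arrays as exchangeable and do not replace independent lines.

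Features named only by a number, left out of the comparisons, also differed: 251 of 2555 passed between knockout and scramble (189 higher and 62 lower, the largest at 4.43), against 2 between scramble and wild type.

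An array stood far from the other 3 of its group in 17 of 570 checks of named genes and list means, where chance gives about 28. In wild type these were UGT2B15 (9.1, others 8.81 to 8.84) and TNFSF10 (7.6, others 7.36 to 7.39) on replicate 1, PKM (11.04, others from 11.12) on replicate 2, SPDEF (10.41, others from 10.57) on replicate 3 and ALKBH1 (9.3, others from 9.6) on replicate 4. In scramble they were KRT7 (10, others from 10.37) and FTO (10.75, others from 10.92) on SCR2 replicate 1, CDK9 (10.7, others from 10.79) and the fatty acid list (9.23, others 9.32) on SCR2 replicate 1b, H1-5 (12.31, others from 12.52) on SCR1 replicate 1 and NHP2 (10.71, others from 10.78) on SCR1 replicate 1b. In knockout they were H2AC13 (11.6, others from 11.78), KDM2A (10.53, others from 10.68) and the G1/S list (8.8, others from 8.95) on KO8 replicate 1, DENND2C (7.16, others 7.24) on KO8 replicate 2, and the basal (8.48, others from 8.54) and NF-kB (7.86, others from 7.9) lists on KO16 replicate 1.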

How the results depend on the processing

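A background covariate, the joint removal of SCR1 replicate 1 and SCR2 replicate 1, and the line correlation of 0.232 were chosen after the results were seen; the other settings were planned. JMJD6 kept its direction in all 30 settings, from -0.73 to -0.56, with -0.65 falling short of a required log2 fold change of 1. No named gene turned its direction. The interferon list kept its call in 27 settings, with a median from 2.68 to 3.31. Probe sets near background set the limit on low genes. The setting for values on a linear scale did not apply. Where a cause is not named below, the cause was not tested.

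Counts of probe sets past the threshold moved by over 1.5 times as follows. For knockout versus scramble (2950) they were 1397 with line means, which leave 5 values in the fit, 4835 with array weights, 362 and 1684 at the stricter thresholds (log2 fold change of 1, adjusted p of 0.01), 6127, 1418 and 1381 without SCR2, KO8 and KO16, and 4575 with the background covariate. For knockout versus wild type (3517) they were 1097 with line means, 7660 with only these groups, 6552 with array weights, 456 and 2079 at the stricter thresholds, 7935, 7942, 1941 and 1643 without SCR1, SCR2, KO8 and KO16, 6232 with the background covariate and 6875 without the scramble pair. For scramble versus wild type (136) they were 280 without a line block, 2 with line means, 425 with fixed line means, 35 with only these groups, 245 with a trended robust prior, 377 with array weights, 20 and 58 at the stricter thresholds, 944, 1102, 61 and 60 without SCR1, SCR2, KO8 and KO16, 908 with the background covariate and 64 with the corrected correlation. For SCR2 versus SCR1 (309) they were 680 with the trended robust prior, 167 with array weights, 52 and 90 at the stricter thresholds and 52 with the background covariate. Array weights gave 1 in KO16 versus KO8.

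Leaving out each array in turn gave 1859 to 5213 for knockout versus scramble, 2252 to 6318 for knockout versus wild type, 46 to 392 for scramble versus wild type, 0 for KO16 versus KO8, 62 to 916 for SCR2 versus SCR1 and -0.68 to -0.59 for JMJD6.

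A replicate block on the numbers 1 and 2 of wild type and knockout (5 arrays) gave 2421 for knockout versus wild type, against 3333 in these arrays without the block. The differences of replicates 1 and 2 correlated at -0.04 between wild type and KO8. These are differences of single arrays and leave out KO16, so a culture or day shared under a number is not excluded.

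In 43 cases the set-test direction of a list turned, all in lists without a call and at an adjusted p of 0.516 or more; the list medians there were as follows. Line means gave 0.06 for cholesterol, -0.09 for fatty acids and 0.02 for Jumonji genes, fixed line means -0.11 for receptor kinases, median centring 0.01 for histones, the dim filter -0.01 for histones and -0.15 for receptor kinases, and fry -0.01 for splicing. Without SCR1 they were 0.12 for cholesterol, -0.02 for fatty acids, -0.07 for splicing, 0.01 for immune and 0.05 for endothelial markers. Without SCR2 they were 0.05 for histones, -0.04 for p53 targets, -0.01 for hypoxia, -0.09 for amino acids, 0.04 for MYC targets, 0.03 for Jumonji genes and -0.18 for receptor kinases. Without KO8 they were 0.01 for histones and 0 for MYC targets, and without KO16 -0.03 for splicing. The background covariate gave 0.11 for cholesterol, -0.07 for splicing, -0.02 for immune and 0.02 for endothelial markers, and removing the scramble pair 0.05 for cholesterol and -0.05 for fatty acids. Over all single arrays left out, with the direction turned by some, the medians ran from -0.05 to 0.05 for histones, -0.11 to 0.03 for MYC targets, -0.05 to 0.04 for Jumonji genes, -0.04 to 0 for splicing, -0.16 to -0.09 for receptor kinases, 0.01 to 0.11 for cholesterol and -0.1 to 0.02 for endothelial markers.

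Of 169 named results, line means ended 45 calls, leaving out KO16 33, KO8 31, SCR1 4 and SCR2 1, only the compared groups 13, the stricter thresholds 81 and 19, and array weights none. Single arrays left out ended up to 17 (SCR2 replicate 1b) and 15 (SCR1 replicate 1b). The corrected correlation ended 10: CGN, CDK9, HNRNPA2B1, RPL7, LDHA, UQCRH, NDUFA9, FBN1 and GNLY in knockout versus scramble, and ADAMTS9 in scramble versus wild type. An estimated correlation ended the call of 6 lists, which the results give. TGF-beta and BMP genes also lost theirs with the dim filter (adjusted p = 0.0627) and without SCR1 (0.146), apoptosis regulators with fixed line means (0.0541), without SCR1 (0.0687), without KO16 (0.0613) and with the background covariate (0.0613), and basal genes without SCR2 (0.0621). P53 targets, endoplasmic reticulum stress genes and ribosomal proteins gained a call without SCR1 (0.00158, 0.014 and 0.0106) and with the background covariate (0.0243, 0.0194 and 0.0243), stress genes also without KO16 (0.0336), while fry, which tests a list against no change rather than against other probe sets, passed 5 lists that the set test did not call (luminal, mesenchymal, amino acid, stress and ribosomal genes), which does not show a difference from other genes.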

Other observations

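The tests of windows of neighbouring genes and the genes named in this part were chosen after the results were seen.

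MTAP, a methionine salvage enzyme next to CDKN2A, rose from 8.47 ± 0.18 in scramble to 10.34 ± 0.06 in knockout arrays (log2 fold change 1.87, SE 0.1, adjusted p = 1e-08, n = 4) and read 8.25 ± 0.12 in wild type. CDKN2B rose by 0.9, DMRTA1 by 0.86, DENND4C by 0.8 and MLLT3 by 0.49, whereas CDKN2A read 7.56 in scramble and 7.54 in knockout arrays. MCF7 is known for a loss of the CDKN2A region, and whether all lines here carry that loss was not tested. MTAP, CDKN2B, DMRTA1 and IFNB1 lie in the window CER1 to ACO1 on chromosome 9, where 9 of 25 genes rose and 2 fell in knockout versus scramble (window median 0.26, and 0.24 with the background covariate). They are themselves among the 9, so this count is no separate evidence of a regional shift. RIGI lies on the same chromosome. In the windows that follow, TOPORS to RPP25L and DCTN3 to FAM221B, 14 and 10 of 25 genes rose and 0 fell (0.34 and 0.22, and 0.35 and 0.26 with the covariate), and in the window before, WASHC1 to ZDHHC21, 12 fell and 0 rose (-0.28, and -0.41 with the covariate). The rises of MTAP (1.87), IFNB1 (at least 3.21) and RIGI (3.68) were larger than any of these window medians. What part of them follows from this region was not tested. Array levels do not show whether a gene is present.

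In 3 windows of neighbouring genes the median was shifted by over 0.25, in each case upward, in both knockout lines against scramble, in both pairings of the lines, and against wild type: SCFD1 to GEMIN2 on chromosome 14, TRPM7 to MNS1 on chromosome 15 and DRAM2 to SYT6 on chromosome 1. They were picked by the same values as the gene calls, so the 39 of their 75 genes that passed in knockout versus scramble are no separate evidence of a regional shift. These held 1.32% of all calls. WASHC1 to ZDHHC21 on chromosome 9 was lower by 0.25 to 0.47 in the same differences and just missed that limit in KO16 minus SCR1.

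Among regulators of the interferon response IRF9 rose by 1.35 and ADAR, an editor of double-stranded RNA, by 0.76. IRF7 rose by 0.45. The values for the feedback inhibitor SOCS1 (-0.04, adjusted p = 0.85) and for IRF3 (-0.03, adjusted p = 0.86) did not pass.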
